A study of Mus musculus with 11 samples.

How the data were processed

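Duodenal epithelium of Neurod1-Cre reporter mice and of GluVenus mice was digested to single cells and sorted into reporter-positive cells and a similar number of negative cells, per the labels' protocols. RNA libraries were made from 2 ng of total RNA with an amplifying kit (Ovation RNA-seq version 2), per the labels' protocols. The submitters' processing notes name CASAVA, TopHat2 2.1.0, Cufflinks 2.2.1 and the build GRCm38, and the annotation release and the use of strand are not given in the sources used here. The deposited table held 1 column of estimated counts per library, with values that were not whole numbers in 848 genes, so the authors' expected counts were rounded to whole numbers before any test. Genes that overlap, antisense pairs and near-identical copies may share reads in such counts.

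The table had 38283 Ensembl genes and 11 columns, each named for 1 sample. Symbols were found for 36337 genes and coordinates for 36425 in the GRCm38 annotation GENCODE vM21. At least 1 count was found for 23468 genes. Libraries held 2279595 to 5722381 counts. The mitochondrial ribosomal genes mt-Rnr1 and mt-Rnr2 are listed at 0 in the 5 Glu libraries and in NeuroD1_negative_6360, and together take 27.5% to 33.9% of the counts of the other 5 libraries. This moves scaling by library totals.

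Counts were tested in edgeR 4.0.16 under R 4.3.3 with filterByExpr, which kept 14332 genes, TMM scaling and the quasi-likelihood test on 4 group means over all 11 libraries, without a replicate block. The 5 contrasts were fitted, and genes were called at a Benjamini-Hochberg adjusted p under 0.05. The SE of a log2 fold change is its size divided by the square root of F. Gene lists, 23 in number with 318 genes, were tested with camera in limma 3.58.1 on voom values with a preset correlation of 0.01, beside an estimated correlation and fry. The groups, contrasts, gene lists, alternatives and the rule for named genes were fixed before the data were examined. The rule took Neurod1 and Gcg first, then the hormone genes, then of each other list up to 4 called members by size of change and up to 2 members that did not pass, then 10 genes each way with the largest change among called genes with an average logCPM of at least 4, a symbol that is no clone name and no overlap of the groups. The rule let the text use fewer genes in its order. Some genes it took are not reported here, and the counts of genes still include them. The text uses at most 3 called members of each list, no member that did not pass outside the hormone list, 5 genes each way and, of the interaction, the hormone genes that passed. These narrower limits were set after the data were examined, when the number of sign changes under the alternatives over a fuller set of genes had been seen, and the counts for the full rule are therefore given beside those for the narrower set. Over the full rule with the genes named after their values were seen, 502 pairs of a gene and a comparison, 148 of 11299 values under the alternatives turned sign, 0 of them for a gene that had passed, and over the 238 pairs of the narrower set 18 of 5344 did.

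A list's camera direction and its median or mean had different signs for 8 combinations of list and comparison, none of which passed. Alternatives were RLE, upper quartile and no scaling factors, no filter and a stricter one, DESeq2 1.42.0, limma voom, robust fitting, glmTreat, the compared groups alone, a replicate block and each library left out. Leaving out mt-Rnr1 and mt-Rnr2 was added after seeing the data. With library totals the median log2 fold change of all genes moved from 0.02 to -0.28 in the NeuroD1 comparison, from 0.12 to -0.19 in the Glu comparison and from -0.14 to -0.51 between the positive populations.

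A group at 0 counts was given a floor of 3 counts over the group, and 1 to 3 counts a ratio with an exact (Clopper-Pearson) 95% interval. Both cover counting error only, since amplified reads without molecular identifiers are not independent molecules. Replicates of a group differed by more than sampling noise in every pair, with a chi-square per degree of freedom of 17.0 to 153, so none was merged. The fit was also tested on simulated counts with 200 changed genes, of which the filter left 48 to 50 at each fold. For the NeuroD1 comparison, on 13877 genes, it recovered 2.04% of genes changed 2-fold, 35.4% at 4-fold, 67.3% at 8-fold and 79.2% at 16-fold. For the Glu comparison, on 13978 genes, it recovered 0% at 2-fold, 26.5% at 4-fold and 59.2% at 8-fold, and for the interaction, on 13877 genes, 24.5% at 8-fold. Between the positives, on 13877 genes, it recovered 63.3% at 8-fold, and between the negatives, on 13972 genes, 60.0%. False calls made up 1.11% of the calls for the NeuroD1 comparison, 5.06% for Glu, 6.98% for the interaction, 9.00% between the positives and 5.95% between the negatives, at an adjusted p under 0.05. The simulated groups shared 1 expression profile apart from the changed genes, while the real NeuroD1 comparison called 2031 genes. These rates therefore describe the simulated setting and cannot be carried over to the real comparisons.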

Results

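RNA was sequenced from cells of the mouse duodenal epithelium that had been sorted by a fluorescent reporter. In one strain the sort followed a Cre-driven yellow fluorescent protein under Neurod1, a transcription factor of enteroendocrine cells, the hormone-producing cells of the gut lining. In the other, GluVenus, it followed a Venus reporter of the proglucagon gene Gcg. The design set the positive cells against the negative cells of each strain, with 3 NeuroD1 positive, 3 NeuroD1 negative, 3 Glu positive and 2 Glu negative libraries. The table held 2279595 to 5722381 counts per library over 38283 genes, of which 14332 had enough counts to be tested. Libraries are named by group and by the number in their label, and the labels do not say that the numbers are separate animals, so p-values measure the spread between these libraries. Values are TMM-scaled CPM (counts relative to the library's size) as mean ± SD, and log2 fold changes are given ± SE.

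Both reporter genes were higher in the positive cells of both strains. Neurod1 (chromosome 2, 79452521 to 79456751 on GRCm38) stood at 487 ± 80.9 CPM in NeuroD1 positive cells (n = 3) and 42.5 ± 7.09 CPM in NeuroD1 negative cells (n = 3). It stood at 461 ± 249 CPM in Glu positive cells (n = 3) and 22.2 ± 9.94 CPM in Glu negative cells (n = 2). Gcg (chromosome 2, 62474530 to 62483650), which encodes the precursor of glucagon-like peptides, was at 11301 ± 934 CPM in NeuroD1 positive cells and 682 ± 98.0 CPM in NeuroD1 negative cells. In Glu positive cells Gcg reached 35685 ± 22090 CPM, against 2719 ± 633 CPM in Glu negative cells. Across the libraries Neurod1 ranged from 394 to 540 CPM in NeuroD1 positive, 35.6 to 49.8 in NeuroD1 negative, 253 to 737 in Glu positive and 15.1 to 29.2 in Glu negative cells. Gcg ranged over 10371 to 12239, 575 to 767, 20200 to 60981 and 2272 to 3166 CPM in the same order.

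**Figure D1:**
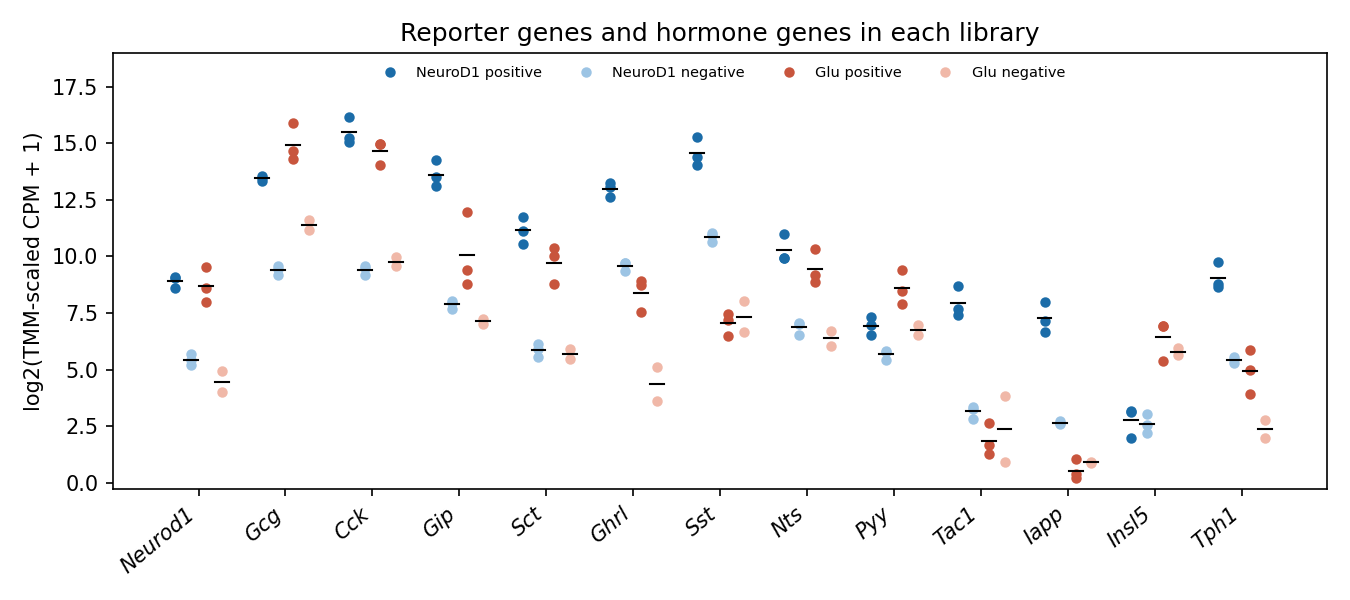
Each point is 1 library, each black line the mean of its group on the plotted scale, and the vertical axis is log2 of TMM-scaled CPM plus 1. Gcg and Cck are high in both positive groups, while Sst at 26120 ± 11844 CPM in NeuroD1 positive cells stands at 137 ± 45.4 CPM in Glu positive cells.

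The first comparison asked which genes mark the NeuroD1 positive cells of the duodenum. Peptide hormone genes rose. Cck, the gene of cholecystokinin, went from 684 ± 102 to 49140 ± 21791 CPM, a log2 fold change of 6.17 ± 0.46. Ucn3 (5.85 ± 0.93), the incretin gene Gip (5.81 ± 0.69), secretin Sct (5.39 ± 0.47), substance P precursor Tac1 (5.02 ± 0.69) and Iapp (4.95 ± 0.53) followed. Gcg rose by 4.05 ± 0.43, somatostatin Sst by 3.79 ± 0.45, Nts by 3.51 ± 0.43, ghrelin Ghrl by 3.41 ± 0.43 and Pyy by 1.29 ± 0.38. Tph1, the enzyme that starts serotonin synthesis, rose by 3.73 ± 0.48. Of the 15 hormone genes measured, 12 rose over all genes tested and 12 adjusted over the list alone. Insl5 (0.23 ± 0.54), Penk (0.05 ± 0.79) and Nmb did not pass.

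The secretory apparatus rose with the hormones. Of 15 granule and prohormone-processing genes, 14 rose (14 adjusted over the list alone), led by Scg2 at 5.41 ± 0.35, Chgb at 4.58 ± 0.46 and the convertase Pcsk1 at 4.28 ± 0.38. Of 15 genes of regulated exocytosis, 14 rose (14 adjusted over the list alone), among them Rab3c (4.32 ± 0.59), Cadps (4.03 ± 0.43) and Stx1a (3.92 ± 0.90). Of 21 enteroendocrine transcription factors, 17 rose (17 adjusted over the list alone). Lmx1a rose by 4.98 ± 0.52 and Neurod1 by 3.52 ± 0.41, and Pax4 was 45.0-fold higher on 2 counts in the negative libraries, with a 95% counting interval of 12.1 to 377. Of 10 genes of the serotonin-producing enterochromaffin cell, 9 rose (9 adjusted over the list alone), with the irritant channel Trpa1 at 6.14 ± 0.59.

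Receptors and channels rose as well. Of 9 nutrient-sensing receptors, 5 rose (6 adjusted over the list alone), including Ffar3 (4.79 ± 0.98), Ffar1 (3.70 ± 1.16) and the calcium-sensing receptor Casr (3.34 ± 0.74). Of 13 hormone and transmitter receptors, 8 rose (10 higher and 1 lower adjusted over the list alone), led by the somatostatin receptors Sstr5 (5.04 ± 0.72), Sstr1 (5.01 ± 0.91) and Sstr3 (4.32 ± 1.17). Of 18 genes of membrane excitability, 11 rose (14 adjusted over the list alone), among them the potassium channel Kcnj11 (4.76 ± 1.32) and the calcium channel Cacna1a (4.06 ± 0.37). Kcnj11 was at 2.89 with adjusted p = 0.206 in edgeR without NeuroD1_positive_6362. Each of these 8 endocrine lists passed camera with the preset correlation, and each passed with an estimated one, the highest adjusted p being 0.0293 for the nutrient-sensing receptors.

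Genes of other duodenal cells were lower in the NeuroD1 positive cells. Of 17 immune markers, 17 fell (17 adjusted over the list alone), among them Cd79a (-5.51 ± 0.73) and Nkg7 (-5.43 ± 1.01). Adjusted p was 0.0239 with an estimated correlation. The immunoglobulin gene Igha, chosen after its values were seen, went from 26688 ± 9709 to 965 ± 420 CPM. Of 12 brush border genes, 9 fell (9 adjusted over the list alone), including lactase Lct (-4.82 ± 0.60), Mep1b (-4.06 ± 0.45) and Mme (-3.97 ± 0.52), with adjusted p = 0.125 with an estimated correlation. Of 15 genes of fat absorption, 9 fell and 1 rose (12 and 1 adjusted over the list alone). Apoa4 (-3.70 ± 0.57), Fabp1 (-3.64 ± 0.48) and Apoa1 (-3.35 ± 0.41) fell, while the lipoprotein receptor Scarb1 rose by 2.07 ± 0.65, and adjusted p was 0.0924 with an estimated correlation. Of 13 nutrient and mineral transporters, 5 fell and 1 rose (8 and 1 adjusted over the list alone). Slc2a2 fell by 3.98 ± 0.77 and the neutral amino acid transporter Slc6a19 rose by 1.47 ± 0.40, with adjusted p = 0.131 with an estimated correlation. Scarb1 and Slc6a19 were named after their values were seen.

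Of 8 Paneth cell markers, 6 fell (7 adjusted over the list alone), with Defa17 at -4.06 ± 0.89 and Lyz1 at -3.63 ± 0.62, and adjusted p was 0.112 with an estimated correlation. Defensin genes are near-identical copies, so their separate counts are uncertain. Of 10 goblet cell markers, 5 fell and 2 rose (5 and 3 adjusted over the list alone). Zg16 (-3.77 ± 0.64) and Spink4 (-3.47 ± 0.59) fell, and Agr2 (1.31 ± 0.38) and Tff3 (1.21 ± 0.36), the latter pair named after their values were seen, rose. The goblet list had adjusted p = 0.300 with an estimated correlation. Of 12 tuft cell markers, 4 fell (7 adjusted over the list alone), with Plcb2 at -4.42 ± 0.77, and adjusted p was 0.0924 with an estimated correlation. Of 14 stromal and endothelial markers, 6 fell (8 adjusted over the list alone), with Acta2 at -2.77 ± 0.84 and Myh11 at -2.70 ± 0.59, and adjusted p was 0.131 with an estimated correlation. Of 19 proliferation genes, Mki67 fell by 1.23 ± 0.36 (none adjusted over the list alone), with adjusted p = 0.157 with an estimated correlation. Of 12 mitochondrially encoded genes, 3 fell (6 adjusted over the list alone), including mt-Co1 at -1.53 ± 0.42, with adjusted p = 0.284 with an estimated correlation.

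The remaining 5 lists did not pass camera. Of 10 stem cell genes Msi1 rose (3.01 ± 0.60), of 12 Notch pathway genes Dll4 rose (3.46 ± 0.82) and Notch2 fell (-1.88 ± 0.48), and of 2 enteric neuron genes Ret rose (4.21 ± 0.47). Of 13 immediate early genes Egr1 passed at 1.00 ± 0.33, though not adjusted over the list alone, and none of 3 pancreatic acinar genes passed.

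In all, 941 genes were higher and 1090 lower in NeuroD1 positive cells at an adjusted p under 0.05 in edgeR's quasi-likelihood test, so that 46.3% of the calls were higher, against 31.5% when libraries were scaled by their totals. By the fixed rule for the largest changes, the cytochrome gene Cyp2j5 (6.61 ± 0.73) and Afp (6.52 ± 0.66) came next after mt-Rnr2 among the genes that rose, and variable segments of immunoglobulin genes such as Ighv1-81 (-6.87 ± 1.01), whose copies are near-identical, led those that fell. The mitochondrial ribosomal gene mt-Rnr2 is listed at 0 in each NeuroD1 negative library and at 15.5% to 17.9% of the counts in the positives, and mt-Rnr1 is listed at 0 in 1 of the 3 negatives and at 33.0% and 33.9% in the others, so no change is read for either. Without NeuroD1_negative_6360 the count of higher genes was 534, without NeuroD1_negative_6361 it was 624 and without NeuroD1_negative_6362 it was 610. The count of lower genes was 720 without NeuroD1_positive_6360 and 722 without NeuroD1_positive_6361. Of the 78 named genes that passed, 11 to 16 lost their call when 1 of the 6 NeuroD1 libraries was left out.

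**Figure D2:**
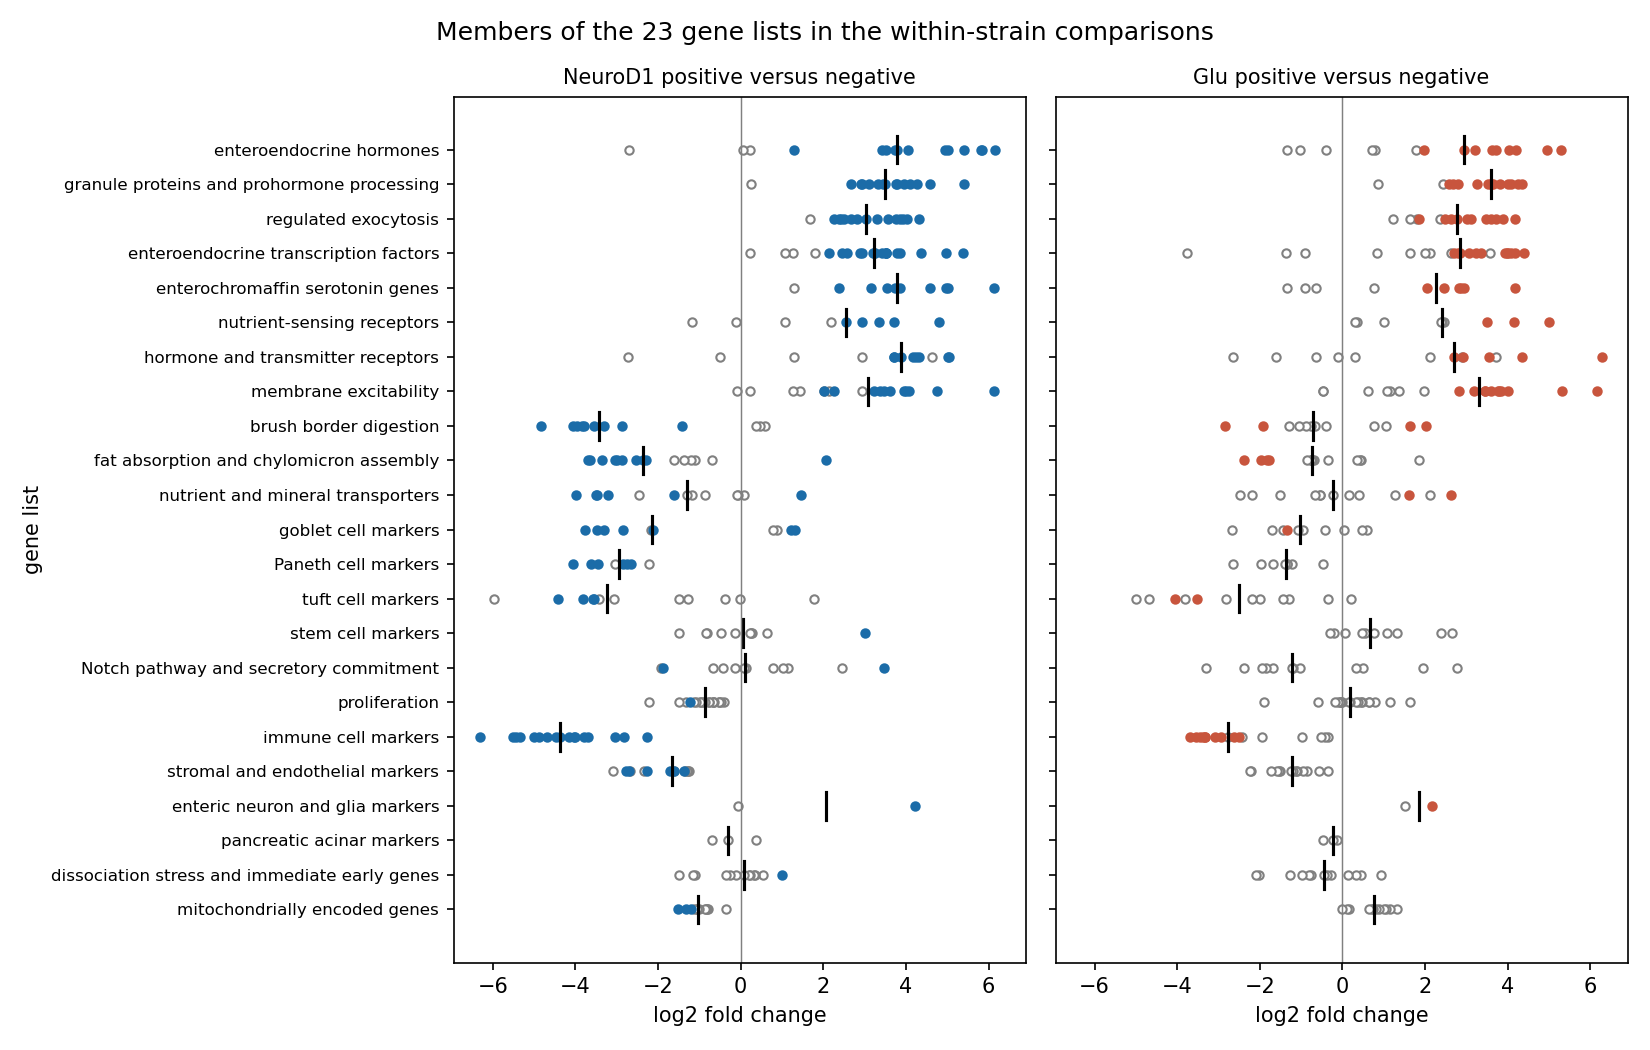
Each point is a gene of the named list at its log2 fold change on the horizontal axis, filled where adjusted p was under 0.05 and open where not, and each black line is the list's median. In NeuroD1 cells the hormone list has a median of 3.79 and the immune list of -4.36, and in Glu cells these are 2.94 and -2.77.

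The second comparison asked the same of the Glu positive cells. Hormone genes again rose, with Cck at 4.94 ± 0.52, Sct at 4.19 ± 0.52, Ghrl at 4.03 ± 0.53, Gcg at 3.71 ± 0.50 and Gip at 3.61 ± 0.73. Nts (3.20 ± 0.51), Tph1 (2.94 ± 0.57), Pyy (1.98 ± 0.44) and Ucn3 (5.29 ± 1.22) rose too. Of 15 hormone genes, 9 rose (9 adjusted over the list alone), while Sst (-0.39 ± 0.45), Iapp (-1.02 ± 0.79), Tac1 (-1.35 ± 0.72), Insl5 (0.79 ± 0.55), Penk (0.71 ± 0.87) and Nmb (1.79 ± 1.47) did not pass. Gip and Ucn3 differed between the Glu positive libraries, Gip at 3996 CPM in Glu_positive_4665, 686 in Glu_positive_5160 and 445 in Glu_positive_5254, and Ucn3 at 48.7, 1.72 and 2.73 CPM. Without Glu_positive_4665 the log2 fold change of Gip was 2.02, and that of Ucn3 was 2.27 and did not pass (adjusted p = 0.0652 in edgeR).

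Of 15 granule genes, 13 rose (14 adjusted over the list alone), including Scg2 (4.36 ± 0.39) and Ptprn (4.09 ± 0.69). Of 15 exocytosis genes, 11 rose (14 adjusted over the list alone), among them Snap25 (4.18 ± 0.51), Rab3c (3.89 ± 0.70) and Cplx2 (3.71 ± 0.43). Of 21 transcription factors, 12 rose (16 higher and 1 lower adjusted over the list alone), with Neurod1 at 4.38 ± 0.51, Fev at 4.19 ± 0.62 and Etv1 at 4.09 ± 0.45. Of 18 excitability genes, 11 rose (12 adjusted over the list alone), with Scn9a at 5.32 ± 1.30 and Scn8a at 4.01 ± 1.06. Of 9 nutrient-sensing receptors, 3 rose (5 adjusted over the list alone), namely Ffar1 (5.01 ± 1.22), Casr (4.16 ± 0.94) and Gpr119 (3.50 ± 0.60). Of 13 hormone and transmitter receptors, 5 rose (6 higher and 1 lower adjusted over the list alone), with Galr1 at 4.34 ± 0.85 and the cannabinoid receptor Cnr1 at 3.55 ± 0.77, though that list missed the threshold with adjusted p = 0.0617. Of 10 enterochromaffin genes, 6 rose (6 adjusted over the list alone), with Gch1 at 2.86 ± 0.66, and adjusted p was 0.0683 with an estimated correlation. Without Glu_positive_5254 the log2 fold changes of Ffar1, Scn9a and Scn8a were 2.62, 3.06 and 2.28 and did not pass, and without Glu_positive_4665 those of Casr and Cnr1 were 2.25 and 2.35.

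Of 17 immune markers, 10 fell (13 adjusted over the list alone), including Fcer1g (-3.68 ± 0.72), Ccl5 (-3.55 ± 0.61) and Tyrobp (-3.46 ± 0.88), with adjusted p = 0.0288 with an estimated correlation. Cd4 stood at 923 CPM in Glu_positive_5254 and at 72.3 to 121 CPM in the other Glu libraries, positive and negative, while Cd8a stood at 15.8 CPM or less in each Glu positive library and at 94.2 and 122 CPM in the Glu negative ones. Of 12 tuft cell markers, Alox5ap (-4.06 ± 1.04) and Trpm5 (-3.53 ± 0.76) fell (7 adjusted over the list alone), with adjusted p = 0.0437 with an estimated correlation. Of 15 genes of fat absorption, 4 fell (4 adjusted over the list alone), including Dgat1 (-2.39 ± 0.43) and Apoa4 (-1.98 ± 0.57), with adjusted p = 0.379 with an estimated correlation. Of 12 brush border genes, 2 rose and 2 fell (2 and 2 adjusted over the list alone), sucrase-isomaltase Sis at 2.03 ± 0.46 and Treh at -2.83 ± 0.82 among them. Of 13 transporters Slc6a19 (2.62 ± 0.49) and the peptide transporter Slc15a1 (1.62 ± 0.46) rose (3 higher and 1 lower adjusted over the list alone), and neither of these 2 lists passed. Of 10 goblet markers 1 fell (1 adjusted over the list alone) with adjusted p = 0.275 with an estimated correlation, and of 8 Paneth markers none passed over all genes (1 lower adjusted over the list alone), with adjusted p = 0.308 with an estimated correlation. No gene of the stromal, Notch or mitochondrially encoded lists passed, alone or over all genes, and their adjusted p values with an estimated correlation were 0.166, 0.336 and 0.439. The camera direction of the mitochondrial list, higher in Glu positive cells, turned without Glu_negative_4665.

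The Glu comparison called 605 genes higher and 346 lower, so that 63.6% of calls were higher, against 42.4% with library totals and 49.0% with upper quartile scaling. With 2 negative libraries the counts rested on each. Without Glu_negative_5254 they were 159 and 138, and without Glu_negative_4665 they were 108 and 79, with the lone library then assumed to vary like the other groups. Of the 54 named genes that passed, 31 lost their call without Glu_negative_5254 and 34 without Glu_negative_4665. The fit on the Glu libraries alone called 195 higher and 145 lower. With the library number as a block they were 512 and 195, and 9 of the 54 lost their call, Treh, Scn8a, Slc15a1 and Alox5ap among them.

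The genes called in the 2 strains overlapped. Of the genes tested in both, 405 were higher in both comparisons, where independent lists of those sizes would share 39.7, and 233 were lower in both, where they would share 26.3. Only 2 genes were higher in NeuroD1 and lower in Glu positive cells, and none the reverse. Log2 fold changes of the 2 comparisons, which share no library, had Pearson r = 0.54 and Spearman rho = 0.46 across 14332 genes, which are not independent replicates.

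The interaction asked where the positive against negative difference itself differed between the strains. It was larger in the NeuroD1 strain for the hormone genes Tac1 (6.37 ± 0.97), Iapp (5.97 ± 0.95) and Sst (4.18 ± 0.61), for Lmx1a (5.88 ± 0.89), a transcription factor of enterochromaffin cells, and for the GLP-1 receptor Glp1r (6.35 ± 1.07). Iapp and Lmx1a averaged 0.903 CPM or less in both Glu groups, so their differences rest on few counts there. Afp, which encodes alpha-fetoprotein, had a fitted difference of 12.15 ± 1.10 that rests on 2 counts in Glu positive cells and is no bound, and Tpbg, named here by the same rule, had 6.95 ± 0.85. The T cell co-receptor Cd28 (fitted -7.13 ± 1.18, on 3 counts in NeuroD1 positive cells), Sash3 (-5.79 ± 0.98) and Ms4a18 (-3.96 ± 0.76) went the other way. Without Glu_negative_4665 the difference of Tac1 was 3.38 with adjusted p = 0.524 in edgeR, and 7 of the 10 named genes lost their call, as did 5 without Glu_negative_5254. Among the other libraries, 3 lost it without NeuroD1_positive_6360 or NeuroD1_positive_6362 and 2 without NeuroD1_negative_6360 or NeuroD1_negative_6362. In all 13 genes were higher and 3 lower, and 1558 genes had an unadjusted p under 0.05. Of 15 hormone genes 3 passed (3 adjusted over the list alone), with adjusted p = 0.104 with an estimated correlation. Of 12 brush border genes none passed over all genes and 9 were lower adjusted over the list alone, with a median of -2.30 and adjusted p = 0.142 with an estimated correlation. Of 12 mitochondrially encoded genes none passed over all genes and 11 were lower adjusted over the list alone, with adjusted p = 0.204 with an estimated correlation. In all 11 lists passed camera with the preset correlation and 0 with an estimated one, while fry called 1. The calls that were higher made 81.2% of all, against 56% with library totals, and the balance turned with DESeq2, at 57 higher and 118 lower, and without a filter on low counts, at 78 and 260. With the library number as a block 11 were higher and 10 lower, and Tac1 and Glp1r lost their call. Single libraries decided the counts, at 5 higher and 0 lower without Glu_negative_4665 and 21 and 31 without Glu_positive_4665, while lower genes numbered 0 without Glu_negative_5254 or NeuroD1_positive_6360, 1 without NeuroD1_negative_6360, 10 without NeuroD1_negative_6361, 13 without Glu_positive_5254 and 16 without Glu_positive_5160.

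The direct comparison asked how the positive populations of the strains differed. NeuroD1 positive cells held more Iapp (8.56 ± 0.67), Sst (7.58 ± 0.53), Tac1 (6.50 ± 0.75), Ghrl (4.50 ± 0.45), Tph1 (4.03 ± 0.48), Ucn3 (3.68 ± 0.81), Gip (2.97 ± 0.60) and Sct (1.36 ± 0.39). Iapp stood at 0.493 ± 0.475 CPM in Glu positive cells, so its fitted value rests on few counts. Glu positive cells held more Insl5 (-3.90 ± 0.55), Pyy (-1.78 ± 0.38) and Gcg (-1.66 ± 0.39). Cck (0.86 ± 0.37), Nts (0.78 ± 0.39), Penk (-0.87 ± 0.78) and Neurod1 (0.08 ± 0.37) did not pass, and the sign of Neurod1 turned with library totals. Of 15 hormone genes, 8 were higher and 3 lower in NeuroD1 positive cells (9 and 4 adjusted over the list alone), with adjusted p = 0.0359 with an estimated correlation. Without Glu_positive_5254 Gcg was at -1.03 and did not pass (adjusted p = 0.0674 in edgeR), and without Glu_positive_4665 Gip was at 4.56 and Ucn3 at 6.70. Insl5 (-3.34 ± 0.57) and Gcg (682 against 2719 CPM) were lower in NeuroD1 negative than in Glu negative cells too. Their differences were thus not confined to the positive cells. From negative to positive cells Gcg rose by 4.05 ± 0.43 in the NeuroD1 strain and by 3.71 ± 0.50 in the Glu strain. Between the negatives 3 of the 15 hormone genes were higher and 2 lower in NeuroD1 cells. Tph1 was among the higher ones. Sst stood at 1892 ± 262 CPM in NeuroD1 negative and at 179 ± 114 CPM in Glu negative cells. Ghrl held 17.2% ± 0.107 of the hormone counts in NeuroD1 negative and 0.558% ± 0.454 in Glu negative libraries. The higher Tph1, Sst and Ghrl of the NeuroD1 strain were thus not confined to the positive cells either.

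Genes of enterochromaffin cells differed as well, though their list is not a separate one. It shares Tph1 and Tac1 with the hormone list, and Lmx1a and Fev with the transcription factors. Of its 10 genes, 6 were higher in NeuroD1 positive cells (7 adjusted over the list alone), with the monoamine transporter Slc18a2 at 4.44 ± 0.58. Lmx1a was 256-fold higher, on 0.460 ± 0.134 CPM in Glu positive cells. The list held with adjusted p = 0.0172 with an estimated correlation. Between the negatives 1 of the 10 was higher (3 adjusted over the list alone). The list's camera adjusted p there was 0.0143 with the preset correlation and 0.259 with an estimated one. Of 21 transcription factors, 3 were higher and 2 lower (4 and 2 adjusted over the list alone), with adjusted p = 0.202 with an estimated correlation. Lmx1a, Hhex (5.49 ± 0.72) and Neurog3 (5.62 ± 1.33) were the higher ones, and Insm1 (-1.39 ± 0.42) and Etv1 (-1.15 ± 0.34), named after their values were seen, the lower ones. Trpa1 (4.23 ± 0.53), Glp1r (5.21 ± 0.80) and the granule genes Pcsk2 (4.35 ± 0.76) and Chga (4.07 ± 0.33) were also higher. Pcsk2, at 4.96, and Chga were higher in NeuroD1 negative than in Glu negative cells too, while Trpa1 and Glp1r did not pass there. Of 9 nutrient-sensing receptors, Gpr119 (-2.01 ± 0.48) and Ffar1 (-3.05 ± 0.92), receptors of lipid products, were higher in Glu positive cells (1 higher and 2 lower in NeuroD1 positive cells adjusted over the list alone), and that list did not pass. Without Glu_positive_5254, where Ffar1 stood at 216 CPM with a mean of 82.4 ± 116 CPM over the 3 Glu positive libraries, Ffar1 was at -0.66 (adjusted p = 0.710 in edgeR), Insm1 at -0.62 and Etv1 at -0.61, and none of these passed. Of 17 immune markers, 12 were lower in NeuroD1 positive cells (13 adjusted over the list alone), including Laptm5 (-5.55 ± 0.72) and Ptprc (-5.23 ± 0.73), with adjusted p = 0.0906 with an estimated correlation. Of 10 goblet markers, 5 were lower (1 higher and 5 lower adjusted over the list alone), including Spink4 (-3.01 ± 0.58, and -1.90 without Glu_positive_5254) and Muc2 (-2.75 ± 0.47), though that list missed the threshold with adjusted p = 0.0548. Of 12 mitochondrially encoded genes, 8 were lower (12 adjusted over the list alone), led by mt-Nd3 (-5.45 ± 0.68), with adjusted p = 0.202 with an estimated correlation. Of 15 granule genes 6 were higher (7 adjusted over the list alone) and of 15 exocytosis genes 5 (5 adjusted over the list alone), and the adjusted p of both was 0.0611 with an estimated correlation. Of 12 brush border genes 4 were lower (6 adjusted over the list alone), with adjusted p = 0.408 with an estimated correlation. In all 13 lists passed camera and 2 kept their call with an estimated correlation.

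Hormone genes took 9.15% ± 0.720 of all gene counts in NeuroD1 positive libraries (n = 3) and 6.79% ± 2.17 in Glu positive libraries (n = 3), against 0.443% ± 0.0481 in NeuroD1 negative (n = 3) and 0.553% ± 0.0636 in Glu negative libraries (n = 2). With mt-Rnr1 and mt-Rnr2 left out the shares were 12.8% ± 1.00 in NeuroD1 positive and 0.582% ± 0.0730 in NeuroD1 negative libraries. Those of the Glu libraries did not change, so the order of the negative groups turned. Within the hormone counts of NeuroD1 positive cells Cck held 43.1% ± 15.2, Sst 23.4% (range 13.6 to 33.6), Gip 12.0% ± 4.79 and Gcg 10.2% ± 2.26. In Glu positive cells Gcg held 51.2% ± 11.9, Cck 41.7% ± 8.08, Gip 2.76% ± 2.96 and Sst 0.244% ± 0.174. The mean share of Gip was 1.09% without Glu_positive_4665, and that of Sst was 0.143% without Glu_positive_5160. In the negative cells Gcg held 63.5% ± 4.39 of the hormone counts in Glu libraries (n = 2) and 15.1% ± 0.463 in NeuroD1 libraries (n = 3). Sst held 4.49% ± 3.41 and 41.8% ± 0.329 there, and Cck 20.7% ± 0.378 and 15.1% ± 0.715. The higher Gcg share and lower Sst share of the Glu libraries were thus not confined to the positive cells. The shares of Gcg, Sst, Gip and Ghrl had a two-sided exact permutation p of 0.1 between the positive groups, the smallest that 3 against 3 libraries allow, and the share of Cck had an exact permutation p of 1. The share of hormone genes in all counts had an exact permutation p of 0.1 between the positive groups, and with TMM-scaled library sizes the shares were 11.3% and 6.72% with an exact permutation p of 0.2.

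In all 456 genes were higher and 709 lower in NeuroD1 positive than in Glu positive cells, so that 39.1% were higher, against 19.3% with library totals. Leaving out 1 library moved the counts to between 245 and 860 higher and 303 and 1322 lower, the top of both ranges without Glu_positive_4665, and the counts were 288 and 303, 245 and 324, and 281 and 350 without NeuroD1_positive_6360, NeuroD1_positive_6361 and NeuroD1_positive_6362. Lower genes numbered 460 without Glu_positive_5254, and the fit on the compared groups alone called 241 and 324. The balance turned with limma voom, at 403 higher and 243 lower. The 5 genes that were higher by most under the fixed rule were mt-Rnr2 and mt-Rnr1, listed at 0 in the Glu libraries so that no change is read, then the stomach gene Muc5ac, Afp and the stomach gene Gkn1. Muc5ac was at least 1965-fold and Gkn1 at least 791-fold higher against a floor of 3 counts over the group, and Afp, on 2 counts in Glu positive libraries, was 8485-fold higher with a 95% counting interval of 2348 to 70070. Muc5ac and Gkn1 were also found in the NeuroD1 negative cells. Fap, on 3 counts over the NeuroD1 positive libraries, was 919-fold lower with a 95% counting interval of 314 to 4460, and Il17a was at least 180-fold lower. The Y-linked gene Kdm5d was at least 102-fold lower. Without Glu_positive_5254, which held 195 CPM of Il17a and 111 CPM of Kdm5d, these bounds were 22.98-fold and 12.5-fold. Of the 62 named genes that passed, 16 lost their call without any 1 of the NeuroD1 positive libraries, 12 without Glu_positive_5254 and 8 without Glu_positive_5160. Strain, batch of libraries and processing cannot be separated in this comparison, and values that were not whole numbers, found in each NeuroD1 library, occurred in at most 2 genes of a Glu library. The Y-linked genes Kdm5d and Ddx3y stood at 0 in every NeuroD1 library and at 2.14 to 111 and 0.140 to 23.1 CPM in the Glu libraries. Xist stood at 260 CPM or more in every library of both strains. A difference in the sex of the mice can therefore not be set apart from strain either.

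The negative populations of the strains differed as well, and there too strain, batch of libraries, processing and, by the Y-linked genes, sex cannot be separated. Gast, the gastrin gene, stood at 1230 ± 147 CPM in NeuroD1 negative cells (n = 3) and at 1 count over the Glu negative libraries (n = 2), a 13648-fold ratio with a 95% counting interval of 2449 to 539122. Muc5ac was at least 1930-fold, the pancreatic phospholipase Pla2g1b at least 1354-fold, Tff2 at least 834-fold and Tff1 at least 808-fold higher. Fap (-6.82 ± 0.62), Insl5 (-3.34 ± 0.57), mt-Nd3 (-5.10 ± 0.69) and Gcg, at the levels given above, were lower in NeuroD1 negative cells, while Chga (2.55 ± 0.36), Pcsk2 (4.96 ± 0.93), Syn1 (3.48 ± 0.72) and Tph1 (3.24 ± 0.58) were higher. Without Glu_negative_5254 mt-Nd3 was at -2.98, and without Glu_negative_4665 Pcsk2 was at 9.89. Of 17 immune markers none passed, alone or over all genes, with a median of -1.14 and adjusted p = 0.191 with an estimated correlation. Of 12 brush border genes none passed over all genes and 7 were higher adjusted over the list alone, with adjusted p = 0.259 with an estimated correlation. In all 13 lists passed camera with the preset correlation and 0 with an estimated one or with fry. In all 52 genes were higher and 18 lower, so that 74.3% were higher, against 54.8% with library totals. Without Glu_negative_5254 the counts were 21 and 6, without Glu_negative_4665 they were 25 and 9, and without NeuroD1_negative_6362 they were 32 and 4. Without Glu_positive_5254 they were 89 and 44, though that library enters only through the filter, the scaling and the shared spread. Lower genes numbered 8 and 9 without NeuroD1_negative_6360 and NeuroD1_negative_6361, and 28 without Glu_positive_4665. Of the 15 named genes that passed, 7 lost their call without Glu_negative_5254, 4 without NeuroD1_negative_6362 and 3 without Glu_negative_4665. Of the 52 genes higher and 18 lower here, 46 and 11 were also called the same way between the positives. Between the positives 456 were higher and 709 lower in all. With so few calls between the negatives, the other genes of the 456 and 709 cannot be taken as free of a difference between the negatives.

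**Figure D3:**
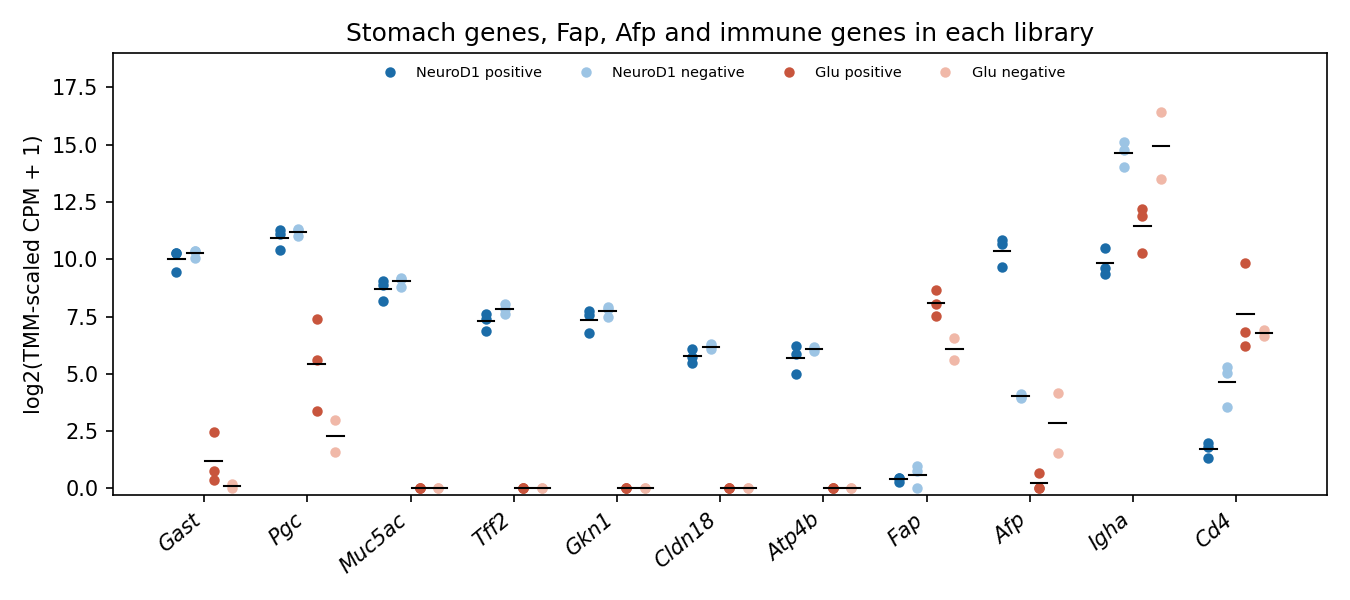
Each point is 1 library, each black line the mean of its group on the plotted scale, and the vertical axis is log2 of TMM-scaled CPM plus 1. Gast lies between 694 and 1323 CPM in all 6 NeuroD1 libraries and at 4.55 CPM or less in the 5 Glu libraries, and Fap lies between 47.8 and 410 CPM in the Glu libraries.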

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

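The tests weighed for the stomach genes, the hormone makeup and Fap, with their bounds, and the list of stomach genes they use were chosen after the results were seen, while the test of the difference and the splits of the libraries were planned.

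A test of the difference itself set 16 genes apart, whose change from negative to positive cells differed between the NeuroD1 and Glu strains (edgeR quasi-likelihood test, adjusted p under 0.05). The fitted log2 differences were 12.15 for Afp, 9.98 for Trpc7, 6.95 for Tpbg, 6.38 for Arg1, 6.37 for Tac1, 6.35 for Glp1r, 5.97 for Iapp, 5.90 for 2810025M15Rik, 5.88 for Lmx1a, 5.68 for Reg4, 4.27 for Fmo2, 4.18 for Sst and 3.77 for Vcan. They were -3.96 for Ms4a18, -5.79 for Sash3 and -7.13 for Cd28. Trpc7, Arg1, 2810025M15Rik, Reg4, Fmo2 and Vcan lie outside the rule for named genes or past its first 5.

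Stomach genes were found in all 6 NeuroD1 libraries, positive and negative, with Gast at 694 to 1323 CPM, Muc5ac at 288 to 580 and Tff2 at 115 to 263. Stomach cells in the digested tissue would be left out of the positive gate, yet the 11 stomach genes other than Gast had a median log2 fold change of -0.31 (SD 0.0784) between NeuroD1 positive and negative cells. That SD is the spread between genes that moved together, and the SE over libraries was 0.32 to 0.95 per gene. The values argue against a fall as large as the brush border median of -3.43, while a smaller fall is not excluded. Duodenal endocrine cells that express Gast would raise it in the positive gate, and its log2 fold change of -0.21 ± 0.46 argues against that. The 12 genes kept closer to 1 ratio to each other over the 6 libraries than random gene sets of like abundance did. Their chi-square per degree of freedom was 1.88, above counting noise, against a median of 33.3 in 1000 such sets, 0% of which were as low. But they were listed after their levels had been seen, so that this decides nothing. Of the 12 genes, 8 had no count in any Glu library. Of the 4 with a count, Pgc stood at 74.1 ± 81.2 CPM in Glu positive and 4.50 ± 3.54 CPM in Glu negative cells. The others, Gast, Gif and Atp4a, stood at 4.55 CPM or less in each Glu library. Whether one common source of stomach RNA or reads supplied the stomach genes of the NeuroD1 libraries stays open.

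The hormone makeup of the NeuroD1 negative libraries was almost constant, with Sst at 41.8% ± 0.329 and Ghrl at 17.2% ± 0.107 of hormone counts (n = 3). A random sample of the cells or reads of the NeuroD1 positive libraries would bring that group's makeup, yet for 2 of 13 hormones, or 15.4%, the mean share lay within the range of the positives. Endocrine cells that fell in the negative gate need not be such a sample, so the differing makeup does not argue against them. Hormones and stomach genes together, 25 genes, kept closer to 1 ratio over the 3 negatives than random sets did. Their chi-square per degree of freedom was 1.60, above counting noise, against a median of 74.1 in 1000 random sets, 0% of which were as low. The stomach genes among them were listed after their levels had been seen. The 13 hormones alone, from a list fixed in advance, had 1.42 against a median of 48.7, the lowest random set being at 8.72. That bears on how constant the makeup was and not on its source. Hormone genes took 0.553% ± 0.0636 of the counts in Glu negative libraries (n = 2), where 9 of the 12 stomach genes had no count. In NeuroD1 negative libraries (n = 3) they took 0.443% ± 0.0481, or 0.582% ± 0.0730 with mt-Rnr1 and mt-Rnr2 left out. A share of this size was thus also found without those 9 genes. Whether the hormone signal has the same source as the stomach genes stays open.

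Fap (chromosome 2, 62500943 to 62574075) lay at 47.8 to 410 CPM in the 5 Glu libraries and at 1.00 CPM or less in the NeuroD1 libraries, and was chosen after its values were seen. Stromal cells in the Glu libraries would bring other stromal genes, whose median log2 fold change between the negatives was -0.44 (SD 1.07) beside -6.82 for Fap, which argues against them. Fap starts 17.3 kb from the end of Gcg, the gene of the reporter, and was higher in Glu positive than in Glu negative cells by a log2 fold change of 2.02 ± 0.48. The neighbour of Gcg carried with the reporter is therefore a candidate explanation, and a strain difference in Fap itself was not tested.

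With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The NeuroD1 comparison called 2031 genes in the real split and at most 0 in the other splits, with 1 split of 10 as large, and the comparison of the positive populations called 1165 and at most 0, with 1 of 10 as large. Each other split mixed both populations within both groups, so their difference went into the spread and few calls could follow. The counts of 0 are therefore no evidence against chance.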

How the results depend on the processing

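The alternatives that left out mt-Rnr1 and mt-Rnr2 were chosen after the results were seen, as was the narrower set of named genes, and the others were planned. Of the genes named that had passed, 56 of 78 kept direction and call under every alternative run for NeuroD1 positive against negative cells, 15 of 54 for Glu, 3 of 10 for the interaction, 36 of 62 between the positives and 6 of 15 between the negatives. Over the full rule for named genes, with those named after their values were seen, 155 of 280 pairs of a gene and a comparison did, and over the narrower set 116 of 219, glmTreat left aside. Of the 23468 genes with a count 14332 had enough counts to be tested, and no fit at another depth was run. The cause of each change below was not tested unless fewer genes or libraries make it plain.

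Counts are given as higher and lower. DESeq2 called 976 and 566 genes for Glu, 57 and 118 for the interaction, 709 and 1121 between the positives and 127 and 43 between the negatives. Without a filter on low counts these were 964 and 587 for Glu, 78 and 260 for the interaction and 153 and 92 between the negatives, with 1248 lower between the positives, and Spearman rho was 0.307. The test against a log2 fold change of 1 (glmTreat) called 494 and 656 for NeuroD1, 246 and 94 for Glu, 208 and 305 between the positives and 8 lower between the negatives. The compared groups alone gave 195 and 145 for Glu, 241 and 324 between the positives and 50 lower between the negatives. limma voom gave 8 and 0 for the interaction and 243 lower between the positives, and the stricter filter 11 lower between the negatives.

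Library totals gave 360 higher for Glu, 11 lower for the interaction, 283 and 1183 between the positives and 38 lower between the negatives, and with mt-Rnr1 and mt-Rnr2 left out 397 and 550 for Glu. The hormone share moved with TMM-scaled library sizes to 11.3% in NeuroD1 positive and 0.426% in Glu negative libraries, and with mt-Rnr1 and mt-Rnr2 left out to 12.8% in NeuroD1 positive and 0.582% in NeuroD1 negative libraries. An estimated correlation left 9 of 18 lists for NeuroD1, 8 of 15 for Glu, 0 of 11 for the interaction, 2 of 13 between the positives and 0 of 13 between the negatives, and fry left 17, 10, 1, 9 and 0 of the same 18, 15, 11, 13 and 13 lists.

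Leaving out each library in turn gave 534 to 1338 higher and 720 to 1419 lower genes for NeuroD1, 108 to 818 and 79 to 369 for Glu, 5 to 21 and 0 to 31 for the interaction, 245 to 860 and 303 to 1322 between the positives and 21 to 89 and 4 to 44 between the negatives. A lone Glu negative library is then assumed to vary like the other groups.

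Signs turned only for values that had not passed and for 1 list. For NeuroD1, Penk went to -0.0119 with RLE, -0.0716 with upper quartile scaling, -0.20 with library totals, -0.0125 with DESeq2, -0.0384 with the compared groups alone and -0.13 with totals and the mitochondrial genes left out, and ranged from -0.17 to 0.26 over the left-out libraries, being below 0 without NeuroD1_positive_6361, NeuroD1_positive_6362 or NeuroD1_negative_6360. Insl5 went to -0.16 with library totals and ranged from -0.0147 without NeuroD1_positive_6362 to 0.58, and Gast ranged from -0.35 to 0.0206 without NeuroD1_positive_6360. For Glu, Penk ranged from -0.0912 without Glu_negative_5254 to 3.16 without Glu_negative_4665, Sst from -0.94 to 0.46 and Tac1 from -2.21 to 1.66, the latter pair above 0 without Glu_negative_4665. Between the positives Neurod1 went to -0.21 with library totals and ranged from -0.21 without Glu_positive_5160 to 0.59, also below 0 without Glu_positive_4665. The mitochondrially encoded list, which had passed for Glu, had an adjusted p from 5.06e-10 to 0.830 and turned without Glu_negative_4665, where it was highest.

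Over all genes the deviations of libraries with the same number had correlations of 0.0459, 0.0104 and 0.00984 for NeuroD1 and 0.0404 and 0.0415 for Glu. The main fit had been planned without a replicate block, so these values did not decide that. With 2 Glu negative libraries the deviations mirror each other, at -0.0404 and -0.0415 for the other number, so they cannot settle the pairing. If a number is 1 animal, the main p-values leave that pairing out. Some genes, chosen after their values were seen, did follow the Glu numbers. Kdm5d stood at 111 and 47.8 CPM in Glu_positive_5254 and Glu_negative_5254 and at 2.14 and 2.66 in Glu_positive_4665 and Glu_negative_4665, Xist at 449 and 260 against 1885 and 1636, and mt-Nd3 at 493 and 625 against at most 115, so whether a number is 1 animal stays open. NeuroD1_positive_6361 correlated better with NeuroD1_negative_6362, at 0.0201, than with its own number. With a replicate block the counts were 914 and 1042 for NeuroD1, 512 and 195 for Glu and 11 and 10 for the interaction, and the lists that passed numbered 17, 16 and 11, of which 17, 14 and 10 had passed without it. The block ended the call of 1 of 78 named genes for NeuroD1, 9 of 54 for Glu and 2 of 10 for the interaction.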

Other observations

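No tests were added here, and the genes were singled out after their values were seen. Several genes outside the lists marked the NeuroD1 positive cells. Reg4, a secreted lectin of the gut, stood at 3194 ± 782 CPM in NeuroD1 positive cells (n = 3) and at 60.6 ± 10.9, 64.6 ± 33.3 and 62.4 ± 1.75 CPM in NeuroD1 negative, Glu positive and Glu negative cells. Tpbg stood at 146 ± 29.1 CPM in NeuroD1 positive cells and at 3.20 ± 0.710 CPM or less on average in the other groups. Afp reached 1408 ± 535 CPM in NeuroD1 positive cells, against 15.3 ± 1.12 CPM in NeuroD1 negative cells, 2 counts over the 3 Glu positive libraries and 9.49 ± 10.7 in Glu negative cells.

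Some T cell genes stood apart in Glu_positive_5254, with Ctla4 at 239 CPM, Il17a at 195 and Ccr4 at 156, where the other Glu libraries held at most 30.0, 8.27 and 24.3 CPM. Cd8a did not, at 11.2 CPM there beside 15.8 CPM or less in the other Glu positive libraries and 94.2 and 122 CPM in the Glu negative ones. Insl5 and the colonic carbonic anhydrase gene Car1 were found in all 5 Glu libraries, at 41.2 to 121 and 68.2 to 219 CPM, and at no more than 8.05 and 32.6 CPM in the NeuroD1 libraries. The pancreatic polypeptide gene Ppy stood at 34.9 CPM in Glu_positive_4665 and at 5.51 CPM or less in every other library. The Y-linked gene Kdm5d stood at 111 CPM in Glu_positive_5254, at 47.8 CPM in Glu_negative_5254, at 2.14 to 7.58 CPM in the other Glu libraries and at 0 in every NeuroD1 library.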
